A study of Homo sapiens with 6 samples.

How the data were processed

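Total RNA from 6 samples labelled as HSC2, an established human oral squamous carcinoma cell line, was labelled with biotin and hybridised to Affymetrix 3′ expression arrays, one array per sample. The groups were taken from the sample labels: 3 samples of cells stably transfected with MALT1 cDNA and 3 of cells transfected with the vector alone, which the labels call mock. Per the labels' protocols, RNA was extracted with Trizol and the labelled RNA was prepared by the array maker's standard protocol. The labels do not say whether the samples of a group came from separate cultures, and they give no batch or date.

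The values deposited by the authors were linear intensity values, one per probe set, already summarised over probes. Their software is not given in the sources used here. From the values themselves, each array had been scaled so that its mean after trimming 2% of the probe sets at each end was about 500.1 to 500.2. The deposited values hold no detection call. The design fixed beforehand allowed for either scale, and because the values were linear they were tested as log2(signal + 1). For dim genes the added 1 makes a fold change smaller than the ratio of the signals, but very low signals can still inflate it.

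The table held 22277 probe sets. After 62 control probe sets were left out, 22215 were tested, with no filter on signal. In the platform annotation used here, 19064 of these had 1 gene symbol, 1043 had several and 2108 had none, and 19052 of the first kind were matched by gene ID to the RefSeq gene table of assembly GRCh38.p14. Genes were named only from probe sets with 1 symbol, which covered 11963 genes. In gene lists and gene order, a gene with several probe sets took the one with the highest mean signal over all 6 arrays. Genes named from the lists or from gene order therefore rest on that probe set alone. All probe sets were counted only for MALT1 and for the 12 rising and 12 falling genes named by the largest difference. Probe sets whose ID ends in x_at or s_at can bind several transcripts, and members of multigene families such as metallothioneins, keratins, serpins and HLA genes are therefore uncertain at the level of the single gene. The positions of the probes along their transcripts were not analysed here. The array names no genome build, so no coordinates are given, and the gene table served only for names and for which genes neighbour each other.

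The level for dim signals was 17.6, the highest signal of the 3 probe sets for the Bacillus trp gene on any of 6 arrays. That signal was on MALT1 replicate 3, and the highest trp signal on each of the other arrays was 6.13 to 14.7. This level was chosen after the data were seen. A probe set at or below it on all 3 arrays of a group has only a bound there. Its change is given as at least N-fold, the geometric mean of the brighter group over 17.6, with the adjusted p of the fit. No fold is given where both groups lie at or below that level. For a list's median, such genes were also set at their bound, and genes dim in both groups at 0.

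Group differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on all 6 arrays, group as the only term and two-sided p-values adjusted by the Benjamini-Hochberg method over all 22215 probe sets. The direction is arrays labelled MALT1 minus arrays labelled mock. The thresholds were an adjusted p under 0.05 and, for a second count, a change of at least 2-fold. All adjusted p-values of genes come from this fit. Simulated data with 22215 probe sets were made from these arrays, and changes were placed only in probe sets above the median signal. There the fit recovered 3 of 50 changed by 0.5 on the log2 scale, 25 of 50 changed by 1, 48 of 50 changed by 2 and 48 of 50 changed by 3. It called 9 of 22015 unchanged probe sets, and recovery of dimmer ones was not simulated. Only 50 probe sets were changed at each size, far fewer than the 7917 that passed in the real data. This makes the adjusted p stricter in the simulation, so these shares are not the recovery to be expected in the real comparison.

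The genes named were set by a rule fixed before the data were examined: MALT1, the 12 rising and 12 falling genes with the largest difference in log2(signal + 1), which dim signals can inflate, among single-gene probe sets that passed the threshold without overlap between the groups, and in each gene list up to 4 members with the smallest adjusted p. Genes named from the chromosomal runs and from the later lists were chosen after their values were seen. The 27 lists, also fixed then, hold CBM complex genes and MALT1 partners, transcripts of MALT1 protease substrates, NF-kappaB targets, epithelial adhesion genes, mesenchymal genes, basal keratinocyte genes, keratinocyte differentiation genes, simple epithelial keratins, matrix proteases and their inhibitors, ERK pathway output genes, the EGFR family and its ligands, mitotic genes, G1/S and DNA replication genes, p53 targets, interferon-stimulated genes, hypoxia and glycolysis genes, integrated stress response and unfolded protein response genes, cholesterol and lipid synthesis genes, TGF-beta and YAP targets, Wnt targets, NRF2 targets, stemness-associated genes, antigen presentation genes, fibroblast, leukocyte and endothelial markers, and reference genes. Each was tested with limma's camera with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 27 lists. Camera with a correlation estimated from the residuals, and fry, were run beside it. On simulated data with noise drawn independently for each probe set, camera called the 1 shifted list of 1 and 0 of 26 others. Such data hold no correlation between genes, so they do not test the preset value.

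A further 10 lists were written after a first look at the data. A test of lost squamous identity, written with them, was dropped after its value was seen because it only restates the fall of the squamous list. They hold genes of luminal breast epithelium, colorectal epithelium, lung alveolar epithelium, hepatocytes, prostate epithelium, urothelium and squamous epithelium, genes of the 17q23 and of the 20q13 amplicon described in the MCF-7 breast cancer line, and genes lost or not transcribed in MCF-7. The median fold change of a list was set against 10000 random lists of the same size, matched on mean signal in 20 bins. Neighbouring genes were compared by the share of pairs changed in the same direction, against 10000 shuffled gene orders.

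Alternatives fixed beforehand were the replicate number as a block, quantile normalization, centring each array on its median, leaving out the dimmest probe sets, eBayes with trend and robust settings, an offset of 16, a plain two-sample test per probe set, 1 value per gene, an adjusted p under 0.01, other list tests, and leaving out each array in turn. An offset of 64, the brighter genes alone, and pairs of genes 5 and 20 apart were added after the data were seen. Figures were drawn with matplotlib 3.10.9.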

Results

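Gene expression was measured on 6 single-colour arrays in cells labelled as HSC2, a human oral squamous carcinoma cell line. On 3 arrays the cells were labelled as stably expressing full-length wild-type MALT1, a paracaspase that works with BCL10 and CARD proteins in NF-kappaB signalling, and on the other 3 as carrying the vector alone (mock). The comparison was made to find genes that respond to MALT1. With 3 arrays per group, the number of arrays limits the precision, and since the samples are not said to come from separate cultures, the p-values measure only the spread between these samples, which may be technical. The median signal was 69.3 to 79.0 on the arrays labelled MALT1 and 64.1 to 68.2 on the arrays labelled mock. Between 25.6% and 31.8% of probe sets on the former and 32.4% to 33.3% on the latter lay at or below 17.6, the highest signal of the bacterial trp control probe sets. The ratio of 3′ to 5′ signal, which rises as RNA or its copy gets shorter, was 3.60 to 4.46 against 3.59 to 3.98 for ACTB and 1.04 to 1.12 against 0.950 to 1.03 for GAPDH.

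The MALT1 transcript itself was lower on the arrays labelled MALT1. Of its 3 probe sets, the one whose ID has no suffix before at read 120 ± 11.3 there against 254 ± 25.0 on the arrays labelled mock (mean ± SD, n = 3 each; log2 fold change −1.08 ± 0.12 SE, adjusted p = 0.0022). The s_at probe set read 182 ± 10.2 against 253 ± 4.34 (log2 fold change −0.47 ± 0.09 SE, adjusted p = 0.0105). The x_at probe set read 180 ± 15.4 against 217 ± 9.55 and did not pass (log2 fold change −0.28 ± 0.10 SE, adjusted p = 0.0969), although it passed with the dimmer probe sets left out (adjusted p = 0.024). On each of the 3 probe sets, every array labelled MALT1 lay below every array labelled mock. These levels go against the labels, so the groups are named by their labels throughout. Probe positions were not analysed here, and a transfected cDNA without the probed part of the transcript would not be measured by these probe sets.

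**Figure D1:**
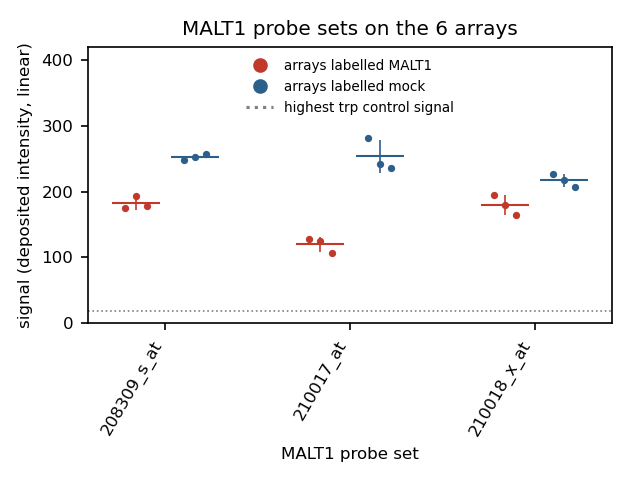
Signal of the 3 MALT1 probe sets (deposited intensity, linear axis) on each of the 6 arrays, with the group mean and SD as lines and the highest trp control signal (17.6) dotted. On the probe set without suffix the arrays labelled MALT1 average 120 and those labelled mock 254.

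The arrays of the 2 groups differed widely. At an adjusted p under 0.05, 7917 of 22215 probe sets (35.6%) differed, 4130 higher and 3787 lower on the arrays labelled MALT1. Of these, 4004 differed at least 2-fold (2101 higher, 1903 lower) and 1728 at least 4-fold (1019 higher, 709 lower). Which direction was the more frequent depended on the processing and on 1 array, with 3179 higher and 4193 lower after median centring, 3964 and 4051 after quantile normalization, 3797 and 3862 with the dimmer probe sets left out, and 3573 and 3757 without MALT1 replicate 3. That array had the fewest probe sets at or below 17.6 (25.6%) and the highest ACTB ratio (4.46). It also held the trp control signal that set the level of 17.6. The groups did not overlap in 11051 probe sets (49.7%), where chance gives 10%. Counted as genes, by the brightest probe set, 2448 of 11963 genes passed with at least a 2-fold change. Among probe sets above the median signal, the SD of the log2 difference between arrays was 0.213 to 0.301 within a group and 1.32 to 1.34 between the groups. The median log2 fold change over all probe sets was 0.08, and −0.05 after centring each array on its median. In 969 of the 4004 probe sets 1 group lay at or below 17.6 on all its arrays (701 higher and 268 lower on the arrays labelled MALT1), so that their fold is only a bound.

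The 12 rising genes named by log2(signal + 1) difference were all dim on the 3 arrays labelled mock, so their folds are bounds and their order is not one of size. GATA3, well above 17.6 in both groups and chosen after its value was seen, rose 67.1-fold, more than several of these bounds. KRT19, a keratin of simple epithelia, read 12410 ± 567 on the arrays labelled MALT1 and 1.25 ± 0.07 on those labelled mock (mean ± SD, n = 3 each), at least 703-fold higher (adjusted p = 2.8e-06). TFF1, a secreted trefoil peptide of gastric and oestrogen-responsive breast epithelium, read 15490 ± 264 against 11.4 ± 2.47, at least 878-fold higher (adjusted p = 2.4e-05), and the carboxypeptidase inhibitor LXN 4272 ± 117 against 1.83 ± 0.54, at least 242-fold higher (adjusted p = 2.3e-05). The chemokine receptor CXCR4 rose in all 3 of its probe sets, to 1293 ± 90.9 on the brightest, at least 73.2-fold higher. RET, a receptor tyrosine kinase, also rose in all 3 of its probe sets, by at least 55.8-fold on the one with the largest change. The other rising genes named were SH3YL1 (at least 136-fold), TBL1X (at least 157-fold, passing in all 5 of its probe sets), TSPYL5 (at least 125-fold), SERPINA3 (at least 65.3-fold), the calcium pump ATP2A3 (at least 56.1-fold, passing in 3 of 4 probe sets), RGS16 (at least 53.7-fold) and the glucose transporter SLC2A10 (at least 34.7-fold).

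The 12 falling genes named in the same way included genes of squamous epithelium and the fatty acid carrier FABP4, and they are not the 12 largest falls, since 8 have a bound only and better measured genes such as IL1B fell further than several of these bounds. FABP4 read 40.2 ± 10.5 on the arrays labelled MALT1 and 2531 ± 32.1 on those labelled mock (log2 fold change −5.98 ± 0.22 SE, adjusted p = 8.2e-05). KLK5, a protease of the stratum corneum, read 23.4 ± 12.6 against 648 ± 6.54 (log2 fold change −4.87 ± 0.40 SE, adjusted p = 0.00073). The metallothionein MT1E read 197 ± 151 against 5807 ± 539 (log2 fold change −5.15 ± 0.57 SE, adjusted p = 0.002), with the 3 arrays labelled MALT1 spread from 79.1 to 368. The lectin CLEC2B read 21.98 ± 7.45 against 638 ± 34.4 (log2 fold change −4.84 ± 0.24 SE, adjusted p = 0.00016). Others were dim on all 3 arrays labelled MALT1 and so have a bound only: the immunoproteasome subunit PSMB8 (at least 20.5-fold lower), EHD2 (at least 14.3-fold), BCHE (at least 11.02-fold), the iron reductase CYBRD1 (at least 6.94-fold), BCL11A (at least 6.89-fold), the squamous serpin SERPINB13 (at least 5.82-fold, passing in 2 of 6 probe sets), the homeobox gene HOXD10 (at least 4.30-fold) and FABP6 (at least 3.72-fold).

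**Figure D2:**
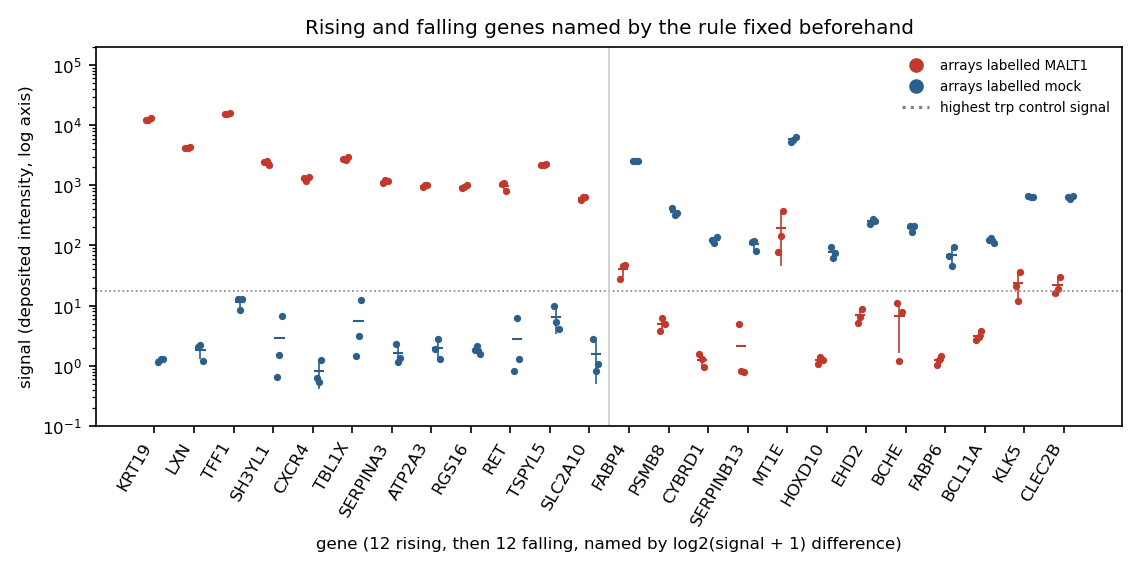
Signal (deposited intensity, log axis) of the 12 rising and 12 falling genes named by log2(signal + 1) difference on each of the 6 arrays, with group mean and SD as lines and the highest trp control signal (17.6) dotted. All 12 rising genes lie below the dotted line on the arrays labelled mock, whereas FABP4, MT1E, KLK5 and CLEC2B lie near or above it in both groups.

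Of the 27 gene lists fixed beforehand, camera with a preset correlation called 13, of which 11 were lower and 2 higher on the arrays labelled MALT1. With an estimated correlation camera called 0 of the 27, with 9 at an unadjusted p under 0.05. Fry called 24, which says that the members of a list move on balance one way, not that they move more than other genes. In lists written after a first look at the data, luminal breast epithelium genes (18 of 24 measured higher, 2 lower and 4 not passing, median log2 fold change 2.33, also with dim members at their bound) and squamous epithelium genes (14 of 18 lower, 0 higher) differed on the same arrays as all the lists that follow. Member counts adjusted over the list alone were the same as those over all probe sets, except where both are given.

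In each of the MALT1 pathway lists more genes fell than rose on the arrays labelled MALT1, on which most luminal breast genes were higher and most squamous genes lower. The lists overlap, with BCL10 in those of the CBM complex and the substrates, and TNFAIP3 and RELB in those of the substrates and NF-kappaB targets. MALT1 itself is among the CBM complex genes that fell. Of 12 measured CBM complex genes and MALT1 partners, 2 rose, 7 fell and 3 did not pass (camera adjusted p = 0.0217, and adjusted p = 0.325 with an estimated correlation; the call was lost when a gene's probe sets were averaged, adjusted p = 0.0572). CARD10, the CARD scaffold of epithelial cells, fell from 3244 ± 106 to 710 ± 48.7 (log2 fold change −2.19 ± 0.09 SE), BCL10 by 1.06 and CASP8 by 3.30 on the log2 scale, while the caspase regulator CFLAR rose (log2 fold change 1.71). Of 8 measured transcripts of MALT1 protease substrates, 1 rose, 6 fell and 1 did not pass (adjusted p = 0.0232, and adjusted p = 0.158 with an estimated correlation). Among them TNFAIP3 fell by 1.64, the deubiquitinase CYLD by 1.02 and RC3H2 by 0.77 on the log2 scale. Of 25 NF-kappaB targets, 1 rose, 12 fell and 12 did not pass (adjusted p = 0.0013, and adjusted p = 0.326 with an estimated correlation). The cytokine IL1B fell from 2605 ± 42.9 to 161 ± 3.41 (log2 fold change −4.01 ± 0.08 SE, adjusted p = 3.3e-05), IL1A fell by 3.12 and CXCL2 by 1.80 on the log2 scale.

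The basal keratinocyte list and the simple epithelial keratins moved in opposite directions, and the keratinocyte differentiation list was not called. Of 12 measured basal keratinocyte genes, 0 rose and 11 fell (12 fell adjusted over the list alone), with a median log2 fold change of −2.15, or −1.95 with dim members at their bound (camera adjusted p = 1.2e-07, and adjusted p = 0.0503 with an estimated correlation). KRT5 fell from 5593 ± 601 to 1003 ± 14.3 (log2 fold change −2.47 ± 0.11 SE, adjusted p = 0.00012), the laminin chain LAMB3 fell by 3.08, and the hemidesmosome integrins ITGA6 and ITGB4 fell by 2.59 and 1.85 on the log2 scale. All 5 simple epithelial keratins rose (adjusted p = 0.00051, and adjusted p = 0.102 with an estimated correlation), with a median log2 fold change of 3.47, or 1.75 with dim members at their bound. KRT8 rose from 332 ± 25.4 to 9874 ± 129 (log2 fold change 4.89 ± 0.09 SE, adjusted p = 3.3e-05) and its partner KRT18 from 6963 ± 505 to 18650 ± 3088 (log2 fold change 1.41 ± 0.15 SE, adjusted p = 0.0016). KRT7 rose too, from 24.6 ± 4.88 to 84.9 ± 15.1. Of 24 keratinocyte differentiation genes, 3 rose, 2 fell and 19 did not pass, and 13 of the 24 were dim on all arrays of a group (adjusted p = 0.853). KLK5 and SPRR1B fell, the latter by 2.89 on the log2 scale, S100A8 rose by 0.80, and S100A7 passed at 20.04 ± 10.7 against 1.75 ± 0.52. Most luminal breast genes were higher on the arrays on which these simple keratins rose. KRT8 and KRT18 belong to both lists. Without its members in lists fixed beforehand, the luminal list had 15 of 21 genes higher and 2 lower.

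Cell adhesion genes split, and more mesenchymal genes fell than rose, although most did not pass. Of 23 epithelial adhesion genes, 8 rose, 10 fell and 5 did not pass, and camera did not call the list (adjusted p = 0.452), whose median log2 fold change was −0.30 and mean 0.01. The tight junction gene CLDN7 rose from 77.5 ± 10.8 to 2245 ± 298 (log2 fold change 4.84 ± 0.15 SE, adjusted p = 6.8e-05), whereas the desmosome genes DSC3, PKP2 and DSG2 fell by 3.27, 2.42 and 2.04 on the log2 scale. Of 23 mesenchymal genes, 1 rose, 9 fell and 13 did not pass (adjusted p = 0.0055, and adjusted p = 0.102 with an estimated correlation). The 1 that rose, ZEB1, was at or below 17.6 on all arrays of both groups, so no fold is given. The transcription factor SNAI2 fell from 3711 ± 135 to 589 ± 15.7 (log2 fold change −2.65 ± 0.08 SE), FSTL1 by 2.76, the hyaluronan receptor CD44 by 2.47 and SPARC by 2.05 on the log2 scale. CD44 also led the stemness-associated genes, of which 2 rose, 3 fell and 7 of 12 did not pass (adjusted p = 0.457). SOX9 and ALDH1A3 fell by 1.39 and 1.43 on the log2 scale, and the transporter ABCG2 rose by 1.39.

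The lists of ERK outputs, TGF-beta and YAP targets and matrix proteases were called lower on the arrays labelled MALT1, and those of the EGFR family and of Wnt targets were not called. Of 18 ERK pathway output genes, 3 rose and 10 fell (11 fell adjusted over the list alone; camera adjusted p = 0.0055, and adjusted p = 0.102 with an estimated correlation). The ERK phosphatase DUSP6 fell from 2510 ± 69.7 to 252 ± 5.96 (log2 fold change −3.31 ± 0.08 SE, adjusted p = 5.4e-05), and PHLDA1, FOSL1 and DUSP5 fell by 3.18, 3.14 and 2.25 on the log2 scale. Of 13 TGF-beta and YAP targets, 0 rose, 9 fell and 4 did not pass (adjusted p = 2.3e-05, and adjusted p = 0.0685 with an estimated correlation), with a median log2 fold change of −1.98. The matricellular protein CCN1 fell by 2.71, AXL by 2.62, and the activin subunit INHBA by 2.61 on the log2 scale, and TGFBI fell from 12330 ± 1561 to 2678 ± 156. Of 21 matrix proteases and inhibitors, 3 rose, 14 fell and 4 did not pass (adjusted p = 0.00037, and adjusted p = 0.0812 with an estimated correlation). MMP13 fell from 1513 ± 81.6 to 224 ± 13.6, the urokinase PLAU from 1504 ± 89.6 to 328 ± 30.5, and MMP10 and cathepsin B (CTSB) by 2.48 and 1.64 on the log2 scale. The EGFR family and its ligands went both ways: 3 rose, 5 fell and 1 of 9 did not pass (adjusted p = 0.215). EGFR fell from 5457 ± 127 to 643 ± 116 (log2 fold change −3.10 ± 0.16 SE), the ligands EREG and NRG1 fell by 3.60 and 2.27 on the log2 scale, and ERBB3 rose by 2.97. Of 6 Wnt targets, 2 rose, 3 fell and 1 did not pass (adjusted p = 0.457). The Wnt antagonists DKK3 and DKK1 fell by 3.25 and 2.15 and LEF1 by 1.56 on the log2 scale, and RNF43 rose by 1.25.

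The mitotic list was called lower and the G1/S and DNA replication list was not called in either direction, with no test of the difference between the lists. Of 22 mitotic genes, 0 rose and 20 fell (22 fell adjusted over the list alone; camera adjusted p = 3.4e-08, and adjusted p = 0.0503 with an estimated correlation), with a median log2 fold change of −0.59. MKI67 fell from 1679 ± 40.01 to 763 ± 49.7 (log2 fold change −1.14 ± 0.09 SE, adjusted p = 0.00062), CENPF from 1409 ± 49.6 to 703 ± 38.98, and TPX2 and UBE2C by 1.15 and 0.98 on the log2 scale. Of 22 G1/S and DNA replication genes, 8 rose and 5 fell (9 and 6 adjusted over the list alone), and camera did not call the list (adjusted p = 0.496). GINS2, MCM3, TYMS and the cyclin CCNE1 rose by 0.84, 0.81, 0.58 and 0.87 on the log2 scale. Of 16 p53 targets, 6 rose and 4 fell (8 and 4 adjusted over the list alone), and the list was not called (adjusted p = 0.256). GDF15 rose from 26.0 ± 5.70 to 310 ± 16.2, the cell cycle inhibitor CDKN1A from 300 ± 38.0 to 1060 ± 31.5, and SESN1 by 1.48 on the log2 scale, while the death receptor TNFRSF10B fell by 1.26.

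**Figure D3:**
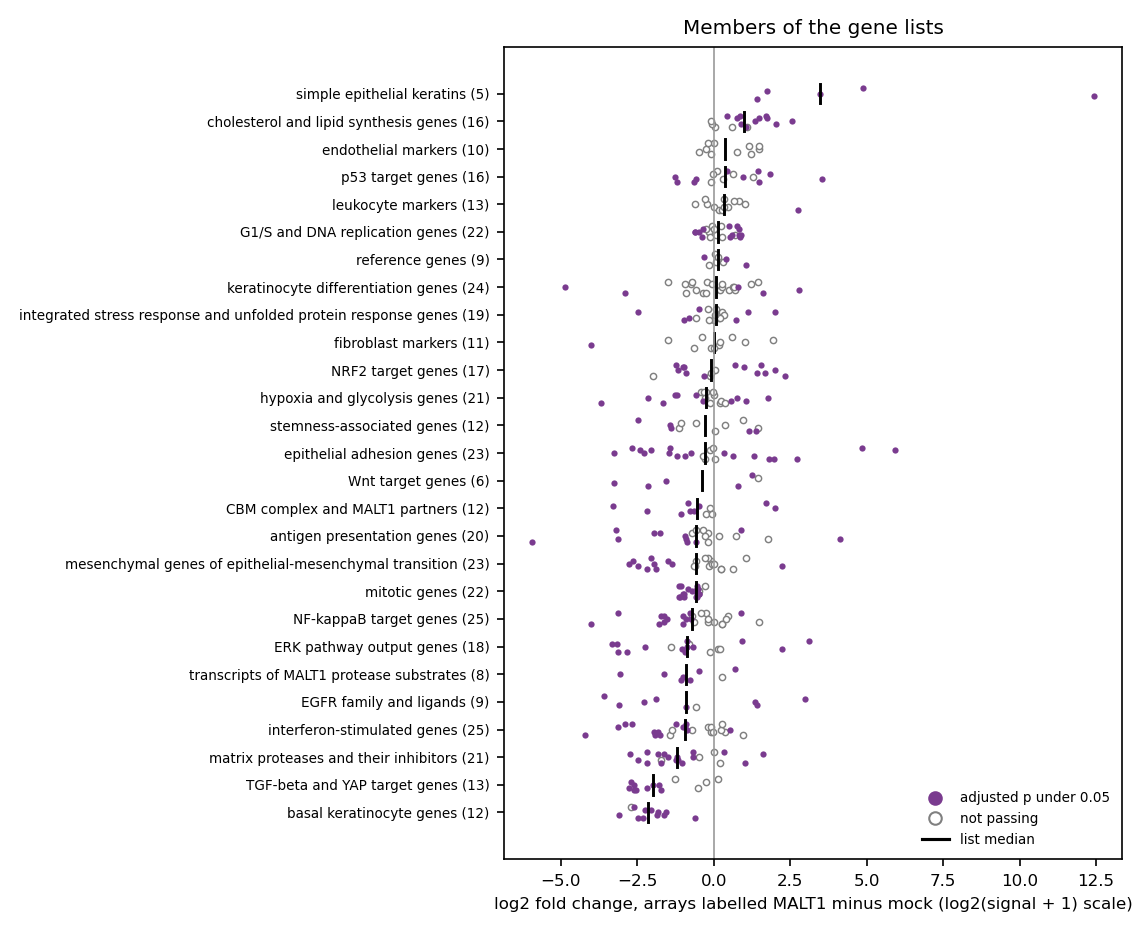
Log2 fold change (arrays labelled MALT1 minus mock, log2(signal + 1) scale) of each measured member of the 27 gene lists, filled where its adjusted p was under 0.05, with the list median as a bar and the number measured in brackets. The basal keratinocyte list has the lowest median (−2.15) and the simple epithelial keratins the highest (3.47). With dim members at their bound these medians are −1.95 and 1.75, and that of the TGF-beta and YAP targets is the lowest (−1.98).

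More interferon-stimulated and antigen presentation genes fell than rose on the arrays labelled MALT1. Of 25 interferon-stimulated genes, 1 rose and 13 fell (14 fell adjusted over the list alone; camera adjusted p = 0.0013, and adjusted p = 0.2 with an estimated correlation). IFIT1 fell from 469 ± 11.6 to 63.5 ± 14.7 (log2 fold change −2.89 ± 0.20 SE), SAMD9 by 3.15, IFI44 by 1.93 and OAS3 by 1.22 on the log2 scale. Of 20 antigen presentation genes, 2 rose and 9 fell (3 and 12 adjusted over the list alone; camera adjusted p = 0.0063, and adjusted p = 0.102 with an estimated correlation). Beside PSMB8, the immunoproteasome subunit PSMB9 fell by 3.14 and the peptidase ERAP2 by 3.19 on the log2 scale, and the class II gene HLA-DRB1 rose from 23.5 ± 6.66 to 418 ± 69.9.

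Among the metabolic and stress lists, only the cholesterol and lipid synthesis list was called. Of 16 measured, 11 rose, 0 fell and 5 did not pass (camera adjusted p = 0.00037, and adjusted p = 0.12 with an estimated correlation). The sterol sensor INSIG1 rose from 399 ± 57.0 to 2355 ± 132 (log2 fold change 2.57 ± 0.13 SE, adjusted p = 0.00018), and the sterol synthesis enzymes IDI1 and SQLE rose by 2.02 and 1.70 on the log2 scale and LSS from 418 ± 19.5 to 1180 ± 75.5. NRF2 targets split, 7 rising and 6 falling of 17 (adjusted p = 0.849, with a median of −0.08 and a mean of 0.17). NQO1 rose from 2491 ± 86.5 to 12430 ± 899, and PGD, ME1 and GCLC rose by 2.01, 1.53 and 1.42 on the log2 scale. Of 21 hypoxia and glycolysis genes, 4 rose and 7 fell (5 and 7 adjusted over the list alone; adjusted p = 0.15). ADM fell from 5753 ± 208 to 447 ± 78.8, and NDRG1, PFKFB3 and P4HA1 fell by 2.16, 1.66 and 1.26 on the log2 scale. Of 19 integrated stress response and unfolded protein response genes, 3 rose and 4 fell (3 and 5 adjusted over the list alone; adjusted p = 0.853, with a median of 0.07 and a mean of −0.02). XBP1 rose from 1295 ± 116 to 5203 ± 473, ATF5 and ASNS rose by 1.12 and 0.73, and the cystine transporter SLC7A11 fell by 0.97 on the log2 scale.

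Many markers of stromal, blood and vessel cells were dim. At or below 17.6 on all arrays of a group lay 7 of 11 fibroblast, 6 of 13 leukocyte and 8 of 10 endothelial markers. The fibroblast marker COL1A1 was brighter, at 71.3 on the arrays labelled MALT1 against 77.1 on those labelled mock. Of 11 fibroblast markers, 0 rose, 1 fell and 10 did not pass (adjusted p = 0.708, with a median of 0.01 and a mean of −0.24). The 1 that fell, LUM, read 0.275 ± 0.13 against 19.4 ± 1.70, at least 1.10-fold lower, and PDGFRB read 23.1 ± 6.51 against 6.5 ± 6.11 (adjusted p = 0.0576). COL3A1 (14.6 against 7.18) and COL6A3 (2.19 against 9.52) did not pass either. Of 13 leukocyte markers 1 rose, CD14, at 17.6 ± 9.86 against 1.51 ± 0.67 and so near the level of the control probe sets in its brighter group (adjusted p = 0.0101; the call was lost under an alternative), and 12 did not pass (adjusted p = 0.662), among them TYROBP (17.3 against 10.0), CD3E (21.0 against 12.2) and FCER1G (23.8 against 16.99). Of 10 endothelial markers 0 rose and 0 fell (adjusted p = 0.662), with ERG at 34.5 ± 17.5 against 13.8 ± 3.32, and CDH5, TIE1 and EMCN at 14.2 or below in both groups. PDGFRB passed under several alternatives (with the dimmest probe sets left out, trend and robust settings, larger offsets, and without mock replicate 2; adjusted p from 0.0072), ERG without MALT1 replicate 1, EMCN without mock replicate 2 and TIE1 without mock replicate 3. Of 9 reference genes, 2 rose, 1 fell and 6 did not pass (adjusted p = 0.457). SDHA rose from 1626 ± 80.7 to 3382 ± 104, TFRC by 0.40 on the log2 scale and HPRT1 fell by 0.32, and GAPDH read 14790 ± 2099 against 11950 ± 1099 (adjusted p = 0.171, and 0.0368 with trend and robust settings). TFRC did not pass after median centring (adjusted p = 0.18), and TFRC and HPRT1 each lost the threshold when single arrays were left out (adjusted p up to 0.0685 and 0.0851).

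Neighbouring genes tended to change in the same direction. Among 11931 genes in chromosomal order, 56.9% of adjacent pairs changed in the same direction, against a mean of 50.4% and a highest value of 52.1% in 10000 shuffled orders (permutation p = 1e-04, the smallest the permutations can give). For genes above the median signal the share was 62.7%, and 56.3% for pairs 20 genes apart, where the highest shuffled value was 52.4%. Over all genes, pairs 20 apart gave 52.9%, against a highest shuffled value of 52.03%. Chromosome 16 had the largest share of genes higher on the arrays labelled MALT1 (70.2%, with 171 passing higher and 46 lower). Chromosome 20 had the smallest (38.1%, with 43 passing higher and 116 lower), followed by chromosome 13 (40.2%, 27 and 83) and chromosome 11 (41.1%, 88 and 234). Among genes above the median signal the order differed, with chromosome 13 lowest (20.9% higher), then chromosome 11 (26.3%) and chromosome 20 (26.8%).

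Runs of 15 consecutive genes above the median signal were searched for after the data were examined. On chromosome 17 all 15 genes from MTMR4 to BRIP1 rose, with a median log2 fold change of 3.13, against a highest run of 1.43 in 100 shuffled orders. Among them, chosen after their values were seen, PPM1D, a phosphatase of the p53 pathway, rose from 568 ± 42.5 to 6146 ± 293, RPS6KB1, the ribosomal S6 kinase, from 797 ± 91.3 to 6992 ± 696, and TRIM37 from 866 ± 14.1 to 10530 ± 450. On chromosome 15 the run from SECISBP2L to ARPP19 held 13 genes that rose and 1 that fell, with a median of 1.53. Runs on chromosome 1, from LRIF1 to SIKE1 (1.36), and on chromosome X, from GTPBP6 to MSL3 (1.32), lay within the shuffled range. On chromosome 11 all 15 genes from ENDOD1 to SLC35F2 fell, with a median of −1.72 against a lowest run of −1.57 in the shuffled orders, and they include YAP1, BIRC2, MMP10 and MMP13. On chromosome 7 the run from DDX56 to PSPH, which includes EGFR, held 10 genes that fell and 1 that rose, with a median of −1.76. The runs from TSPAN13 to OSBPL3 on chromosome 7 (−1.5) and from WEE1 to RRAS2 on chromosome 11 (−1.38) lay within the shuffled range.

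**Figure D4:**
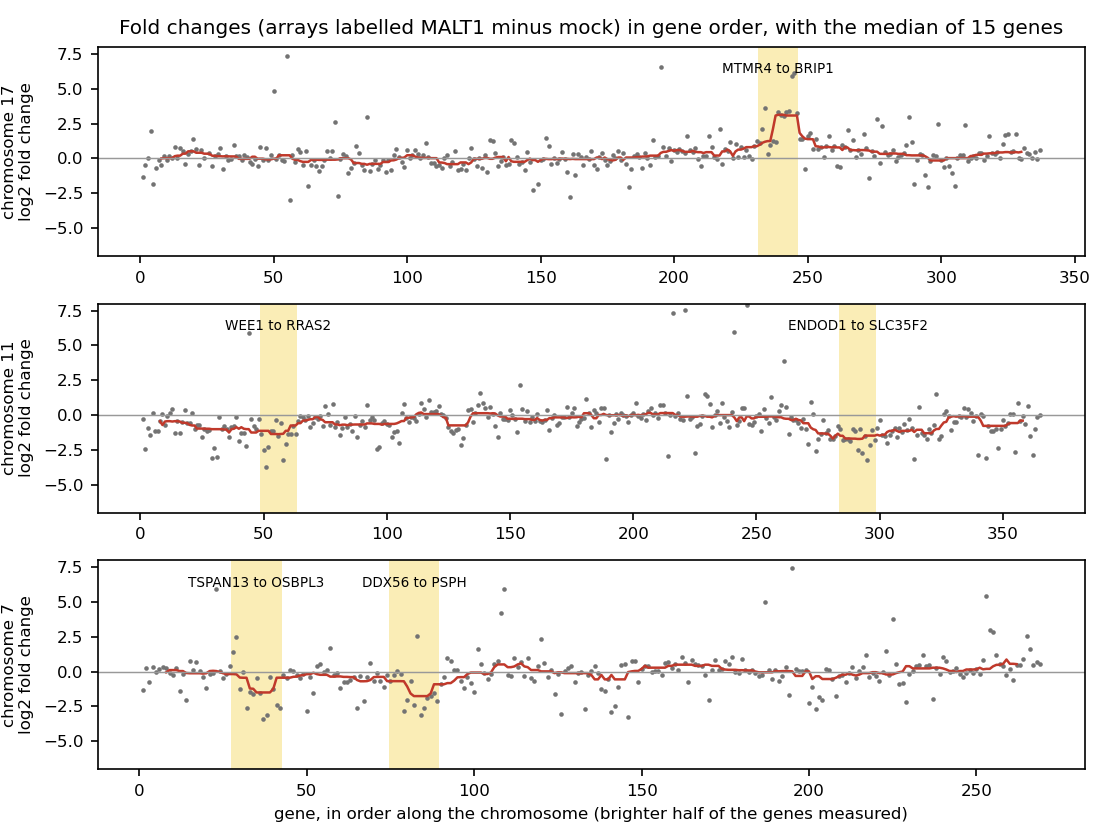
Log2 fold change (arrays labelled MALT1 minus mock, log2(signal + 1) scale) of genes above the median signal in their order along chromosomes 17, 11 and 7, each point a gene, with the running median of 15 genes as a line and runs named in the text shaded. The run from MTMR4 to BRIP1 reaches a median of 3.13, and the runs from ENDOD1 to SLC35F2 and from DDX56 to PSPH reach −1.72 and −1.76.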

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

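Every MALT1 probe set kept its direction under each alternative that tested it. No named gene or gene list that passed in the main run or in the alternative reversed. Reversals among those passing in neither were not counted. An offset of 64 and the gene pairs other than adjacent ones were chosen after the data were seen. Counting 1 value per gene gave 5107 changed genes and 2486 over 2-fold, fewer because fewer values were tested, and an adjusted p under 0.01 gave 4962 changed probe sets. With an offset of 64, 2198 probe sets passed 2-fold, an offset that shrinks the folds of dim genes; with the dimmer probe sets left out 2676 of 11107 did. The list tests gave 13 calls, 0 with an estimated correlation, 24 with fry and 12 with the mean over a gene's probe sets. The s_at probe set of MALT1 kept a log2 fold change of −0.47 but lost its call at the adjusted p threshold of 0.01 (adjusted p = 0.0105, over all alternatives 0.00084 to 0.0543), because that threshold is stricter. The x_at probe set gained a call at −0.28 with the dimmer probe sets left out (adjusted p = 0.024, fewer probe sets being tested) and at −0.21 with an offset of 64 (adjusted p = 0.041; over all alternatives up to 0.232); the cause of the second was not tested.

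The replicate numbers of the labels showed no clear pairing of the samples. Deviations of same-numbered arrays from their group means correlated at 0.015, −0.026 and −0.014 over all probe sets. Among probe sets above the median signal they correlated at 0.044, 0.007 and 0.045, and MALT1 replicate 2 did not correlate best with its own number. With the number as a block, 5808 probe sets passed (5601 of the 7917), 3645 at least 2-fold, 13 lists were called, and the s_at probe set of MALT1 lost its call at −0.47 (adjusted p = 0.0543), as did CD14 (0.0538), TFRC (0.0835) and HPRT1 (0.0962). Leaving out each array in turn gave 6165 to 7330 changed probe sets, 3716 to 3944 over 2-fold, 13 lists each time, 56.8% to 57.1% same-direction neighbours, and log2 fold changes of −1.13 to −0.997 for the MALT1 probe set without suffix, −0.52 to −0.44 for s_at and −0.34 to −0.21 for x_at.

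Quantile normalization gave 8015 changed probe sets (7431 of the 7917), median centring 7372 (6938), trend and robust settings 9042 (7601), an offset of 16 gave 8587 (7807), and a plain two-sample test 7612 (7162); 0 calls turned direction. Over 2-fold, lower calls outnumbered higher ones after centring (2266 against 1809), quantile normalization (2101 against 1902), with the dimmer probe sets left out (1406 against 1270), with an offset of 64 (1109 against 1089) and without MALT1 replicate 3 (2046 against 1898), and not under the other settings. For named genes, 2085 of 2111 combinations of gene and alternative kept their side of the threshold, 17 lost a call and 9 gained one. For gene lists 404 of 429 kept it, 14 lost and 11 gained a call. Direction was compared only where the main run or the alternative passed, and it never turned there. Same-direction neighbours were not recomputed with the block, the variance settings or the offsets. Array signal limits the dim genes: 25.6% to 33.3% of probe sets lay at or below 17.6.

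The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 7917 changed probe sets and 4004 over 2-fold, and the highest of the others 0 and 0 with limma, with at most 748 at an unadjusted p under 0.05; it gave 13 lists, and the highest other 10. In each case 1 of the 10 splits, the real one, gave as many.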

Other observations

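The tests of another cell line, of the authors' scaling, of noise in dim probe sets, of a small share of mock-like RNA, of exchanged labels, of the cDNA outside the probes and of the 17q23 amplicon alone were chosen after the results were seen, as were the 10 lists used here.

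Genes of luminal breast epithelium spanned a wide range of signal on the arrays labelled MALT1. ESR1, the oestrogen receptor, read 1765 ± 45.0 there against 115 ± 4.65 on the arrays labelled mock (adjusted p = 4.8e-05), its pioneer factor FOXA1 740 ± 30.8 against 9.86 ± 6.503 (at least 41.9-fold higher), MLPH 2145 ± 97.6 against 37.4 ± 15.4 and the zinc transporter SLC39A6 14260 ± 781 against 3133 ± 33.3. GATA3, a luminal transcription factor held here in the urothelium list, read 12860 ± 1303 against 191 ± 25.7. TBX3 read 124 ± 3.11 against 1.75 ± 0.63 (at least 7.01-fold higher), and PGR was dim on all 6 arrays. In the luminal list 18 of 24 measured genes were higher and 2 lower (percentile 100 among matched random lists); 17 of the 24 were above 17.6 on at least 1 array labelled mock, and 3 are also in lists fixed beforehand. Of the other lists, the colorectal one had 3 higher and 0 lower of 13 (percentile 93.5), lung alveolar 1 and 0 of 9 (59.2), hepatocyte 0 and 0 of 13 (66.2), prostate 2 and 1 of 7 (86.0) and urothelium 2 and 0 of 9 (20.4), with medians of 0 once dim genes were set at their bounds.

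In the squamous list 14 of 18 measured genes were lower, 0 higher and 4 did not pass, with a median log2 fold change of −2.06, or −2.03 with dim members at their bound, below all matched random lists; without the members that are also in lists fixed beforehand, 12 of 16 were lower. FGFBP1, which had been seen before the list was written, fell from 3450 ± 141 to 242 ± 20.6, SERPINB5 from 4268 ± 205 to 590 ± 53.2, TRIM29 from 1049 ± 33.7 to 145 ± 25.1 and S100A2 from 18180 ± 2357 to 10430 ± 478. Several of these genes thus stayed well above 17.6 on the arrays labelled MALT1.

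The difference between the groups was broad, with 4004 probe sets over 2-fold, and joined higher luminal breast genes to lower squamous genes; scaling by the authors is argued against, since 8015 probe sets passed after quantile normalization, 7431 of them among the 7917, and so is noise in dim probe sets, since 23.98% of the probe sets above the median signal passed with at least a 2-fold change. A candidate explanation is that the arrays labelled MALT1 measured another cell line of luminal breast type, since the luminal list's median lay at percentile 100 while the colorectal, lung, hepatocyte and prostate lists reached at most 93.5; KRT19, TFF1, RET and GATA3, seen before, were left out of that list, which without its members in lists fixed beforehand had 15 of 21 genes higher, and the labels name no sort. Whether the RNA on those arrays also holds a small share like that of the arrays labelled mock stays open. On the arrays labelled mock, 128 genes had a signal of at least 1000 and were at least 4-fold lower on those labelled MALT1. Of these, 1 was left with under 2% of its signal, against 25 of 108 genes the other way round (Fisher's exact test, two-sided, p = 9.64e-09). This asymmetry meets what was written for such a share, but it would also arise if the groups differed in which genes are silent. The test also counts genes as independent. No single share covers all genes, since the median left was 15.6% and FABP4 was left with 1.59%. A share common to all genes could not exceed what FABP4 kept, which is below the 2% used in the test. By itself a share that small would not hold the other genes above 2%, so the test cannot decide whether one is present. A broad effect of MALT1 in these cells and a divergence of the selected lines stay open, as neither was tested and no DNA was measured.

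MALT1 was lower on the arrays labelled MALT1. Labels of the 2 groups exchanged would need a strong excess on the arrays labelled mock, and the largest difference, −1.08 on the log2 scale, neither reaches the 4-fold set for that nor excludes it, so that this cannot be told apart from other explanations. A transfected cDNA outside the probed part of the transcript stays open too: 0 MALT1 probe sets were higher past the threshold on the arrays labelled MALT1, and the probe positions that would decide were not analysed here. Arrays of another line as above may give the same values.

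Neighbouring genes changed in the same direction. Tandem gene families as the whole cause are argued against by pairs 20 genes apart. Among genes above the median signal, such pairs still shared direction in 56.31% of cases against at most 52.4% in 10000 shuffled orders. Over all genes the share was 52.9% against at most 52.03%. The first value meets what was set for regional copy number differences between the cells of the 2 groups. Both this distance and the brighter genes alone were added after the data were seen. Gene orders were shuffled over the whole genome, so shifts of whole chromosomes would also raise the share of same-direction pairs. Among genes above the median signal, 20.9% were higher on chromosome 13 and 70.1% on chromosome 16. Differences between regions of a chromosome are therefore not shown by this test. Whether the run on chromosome 17 is the 17q23 amplicon described in MCF-7 stays open: 13 of 13 measured genes of that list were higher (percentile 100), but 11 of them lie in the run itself, so that the list restates the run, and only 2 lie outside it. The test of both MCF-7 amplicons together stays undecided, because the 20q13 list had 4 genes higher and 5 lower of 18 (percentile 71.6). A copy gain in the cells of both groups would not show there, and no DNA was measured. Of the genes lost or not transcribed in MCF-7, 2 of 3 measured were lower, CDKN2A and MTAP by 3.53 and 3.51 on the log2 scale, while CDKN2B was dim on all 6 arrays and leaves that test open too.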
